A study of Enchytraeus albidus with 21 samples.

How the data were processed

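The data are 21 single-colour (Cy3) arrays of a custom Agilent design, hybridised with labelled RNA from whole adult worms, 10 worms per replicate, with 0.5 µg of RNA per labelling. The replicates are biological, since worms of each replicate were kept in separate vessels or sampled separately from the culture, per the labels' protocols. The arrays fall into 6 groups: worms from culture (3 arrays), 2-day water control (3) and 2-day acetone (3) in experiment 1, and 2, 4 and 8 days in control soil (4 each) in experiment 2. Groups and replicate numbers were taken from the sample titles.

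Spot intensities were extracted with Agilent Feature Extraction, per the file headers: version 10.5.1.1 with scanner model G2505B for 19 arrays and version 10.7.3.1 with scanner model G2505C for 4-day replicates 1 and 2. The submitters' processing notes name version 10.5.1.1. The processed intensity of a spot is background-subtracted and detrended within its array, and is not normalized between arrays, per the file headers. The raw median intensity of spot and local background, and marks for spots well above background, saturated or non-uniform, come from the same deposited files. A further deposited table holds the authors' log2 values, 1 per probe and array, with 144 missing values. Its columns correlated with the log2 processed signal of the same arrays at 0.970 to 0.999, so its scale and direction are known. Their medians ranged from 7.92 to 7.98 in experiment 1 and from 7.53 to 7.65 in experiment 2. Quartiles differed by at most 0.0819 among arrays of experiment 1 and 0.144 among those of experiment 2, but by 0.471 over all arrays. The values were thus normalized per experiment, and this table was used only within an experiment. How the authors summarised spots and which normalization they applied is not given in the sources used here.

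Each array held 15744 spots, 536 of them controls, and 15208 spots of 1035 worm probes. Control spots and spots marked as outliers (2.79% to 6.37% per array) were left out, and saturated spots were kept (0 to 53 saturated probes per array). The log2 processed signals of a probe's spots were averaged, and the 75th percentile of the array's log2 signals over worm spots was subtracted. A probe counted as well above background on an array when a share of at least 0.5 of its usable spots was. A probe was tested when it was well above background on every array of at least 1 group in the fit, which left 883 probes in experiment 1, 859 in experiment 2 and 889 between the experiments. Where a probe was well above background on no array of a group, its fold is given as a lower bound.

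Arrays 2 and 4 of the 2-day group of experiment 2 were nearly identical and were averaged to 1 sample after the data were seen; 4 samples had been planned. Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the probes of a comparison and a threshold of 0.05. The 3 groups of an experiment shared 1 fit without covariates, and the comparison of the experiments used its 2 groups. The 7 comparisons were control soil against culture, acetone against water control, 4 against 2, 8 against 2 and 8 against 4 days, any difference among times (moderated F), and experiment 2 against experiment 1 at 2 days. Adjusted p-values in the text come from these fits. The fits were tested on simulated data with 200 changed probes. For acetone they found 67.2% of probes changed by 1 log2 unit, 95.2% of those changed by 2 and 98.9% of those changed by 3. For 4 against 2 days they found 23.4%, 68.5% and 87.6%. Between 3.32% and 4.86% of calls were false over all comparisons. These simulations drew each probe independently, with 1 spread for all groups. The real probes are linked and the real groups differ in spread, so the simulated rates need not hold for the real calls.

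Before the data were examined, 22 lists of genes had been fixed as words to search in probe annotation. The files hold no annotation: the gene name column repeats the probe identifier for all 1035 probes, so no list had a member and none was tested. For the same reason the rule for named probes took its planned form for arrays without annotation. At most 2 probes higher and 2 lower were named per comparison, those with the largest log2 difference among calls whose groups did not overlap. Where fewer than 5 probes passed, those with the smallest unadjusted p in each direction were named and given as values. Probes named outside this rule are said to be so. In place of the lists, and after seeing the files, 4 classes were read from the form of the identifiers (345 with Met, 198 with Pest, 171 contigs, 321 with a plate position only). The files do not spell out what Met and Pest stand for. The classes were tested with limma's camera (preset correlation 0.01, and estimated).

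Alternatives fixed beforehand were quantile normalization, centring on the median, the authors' values, no filter and a stricter filter on dim probes, outlier spots kept, an intensity trend in eBayes, other sets of samples in the fit, the replicate number as a block, scan day and slide as random blocks (duplicateCorrelation), and leaving out each replicate. Scan days (10) and slides (15) were read from the file headers and numbered. No scan day held both groups of any comparison. Added after seeing the data were normexp on the median signals (offset 50), the near-identical arrays as separate samples, the 3 dimmest arrays of experiment 2 left out, and the 4-day arrays of either scanner alone.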

Results

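Transcript levels were measured in whole bodies of Enchytraeus albidus, the white potworm, a small annelid that lives in soil and decaying matter and serves as a test species in soil ecotoxicology. Each array was hybridised with labelled RNA from 1 replicate of 10 adult worms with a developed clitellum, the glandular band of mature worms. In experiment 1, 3 replicates were taken straight from the laboratory culture at day 0, 3 spent 2 days in moist control soil, and 3 spent 2 days in soil spiked with acetone. In experiment 2, 4 replicates each spent 2, 4 or 8 days in control soil. Test vessels held 25 g of soil at 20 °C, with 16 h of light and 8 h of dark. The single-colour array carried 1035 worm probes, each in 14 or 15 spots. Between 599 and 974 probes were well above background on an array (median 886). The fewest were on culture replicate 3, against 869 and 974 on the other culture arrays. The signal at the 75th percentile of the spots ranged from 868 to 3720, and was lowest on 2-day replicates 1 and 3 and 8-day replicate 3 of experiment 2 (868, 1150 and 973). The number of arrays, 3 or 4 per group, limits the precision. All levels below are log2 signals relative to the 75th percentile of the same array, so that a probe at 0 is as bright as that percentile. The files do not pair probes with genes, so probes are given by their identifiers and what they encode is not stated.

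The design first describes how much worms kept under nominally equal conditions varied. In experiment 1, probes were steady between replicates, with a median SD over 894 probes of 0.204 log2 units in the 2-day water controls, 0.290 in worms from culture and 0.366 with acetone (n = 3 each). In experiment 2 the median SD was 0.591 at 2 days (n = 3 samples; 0.220 without the averaged pair described below), 0.695 at 4 days (n = 4) and 0.540 at 8 days (n = 4). The SD exceeded 1 log2 unit for 1.45% to 3.69% of probes in the groups of experiment 1 and for 19.6% to 25.1% in those of experiment 2. A probe that varied widely was P2_B7_T7_1328934, at −2.31 in 1 of the 3 water controls of experiment 1 and not well above background in the other 2. Contig129 varied less in experiment 1, with an SD of 0.20 in culture, 0.31 in the water controls and 0.55 with acetone. In experiment 2 its SD was 1.73 at 2 days, 3.58 at 4 days and 3.14 at 8 days.

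Arrays 2 and 4 of the 2-day group in experiment 2 were nearly identical. Their log2 differences had a spread (median absolute deviation, MAD) of 0.0647, against 0.0274 from the scatter of the spots alone, and 0% of probes differed over 2-fold. The next closest of the 210 pairs of arrays had a MAD of 0.224. These 2 arrays were on different slides and were read on different scan days. They were therefore averaged and counted as 1 sample, which leaves 3 samples at 2 days and 20 in all. Pairs of other 2-day arrays in that experiment had MADs of 0.430 to 1.24.

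**Figure D1:**
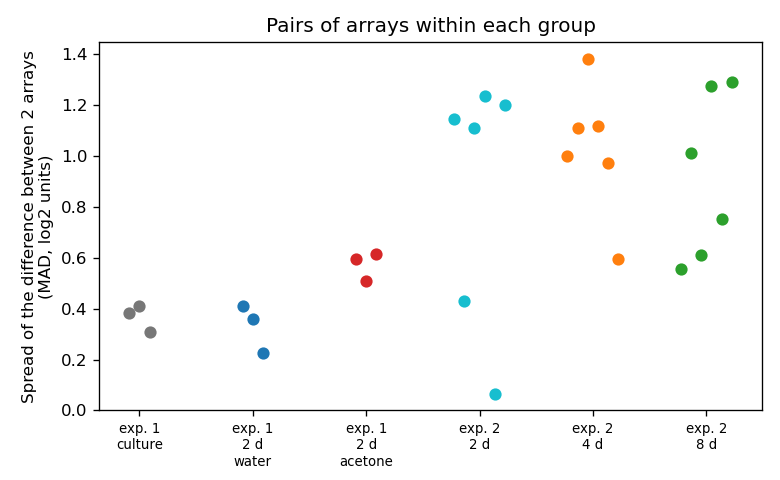
The spread (MAD, log2 units) of the difference between 2 arrays is plotted for each pair of arrays within the 6 groups, 1 point per pair. Pairs in experiment 1 lie between 0.224 and 0.615, and pairs in experiment 2 reach 1.38, with 1 pair of 2-day arrays at 0.0647.

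On the first principal component (31.3% of the variance), 2-day replicates 1 and 3 and 8-day replicate 3 of experiment 2 lay between 27.7 and 34.2, away from the other 17 samples, of which 4-day replicate 2 came closest. These were the 3 samples with the dimmest arrays of that experiment. The second component (15.9%) held the 3 acetone samples at 10.3 to 11.4 and the worms from culture at −14.0 to −11.8, but did not set these apart from the rest: 8-day replicates 2 and 4 lay at 17.1 and 15.8 and water control replicate 3 at −15.1.

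**Figure D2:**
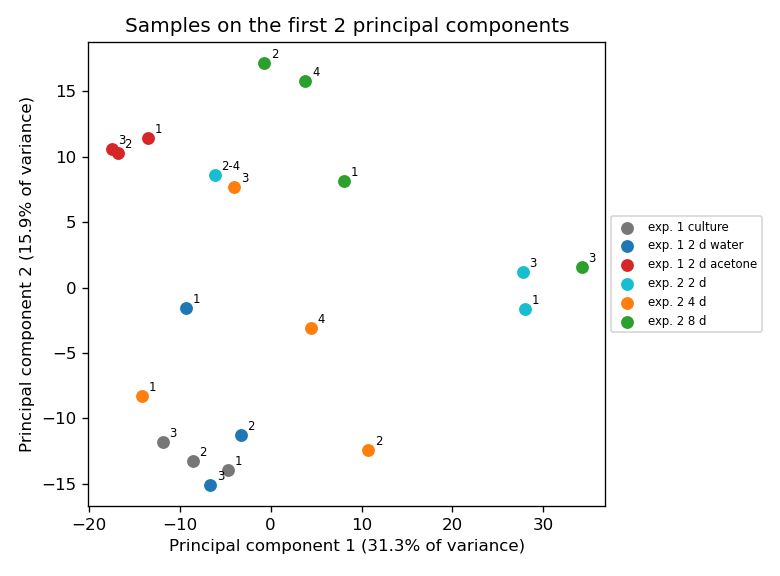
Each point is 1 of the 20 samples on the first 2 principal components of the log2 levels (axes in component units, with the percent of variance), coloured by group and numbered by replicate; 2-4 is the averaged pair. The 3 samples at the right, between 27.7 and 34.2, are 2-day replicates 1 and 3 and 8-day replicate 3 of experiment 2.

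The first comparison of the design asked what the move from culture to control soil does. After 2 days in soil, P5_D7_T7_1329838 was 2.47-fold higher than in worms from culture (log2 difference 1.31 ± 0.18 SE, adjusted p = 0.0341). Its level was 2.29 ± 0.14 (SD, n = 3) in soil and 0.98 ± 0.16 (SD, n = 3) in culture. Of 883 probes tested, 1 passed, this one. P4_C2_SP6_1371456 differed by 0.97 and P3_A9_SP6_1371430 and Ealb_Pest_P1_A4_SP6_2090839 by −1.19 and −1.08, none of them past the threshold (adjusted p = 0.109 for each). The groups did not overlap for 288 of the 883 probes, against 10% by chance, and 154 had an unadjusted p under 0.05. The median log2 difference over all probes was 0.12. The call was lost when any of the 6 replicates was left out (0 probes) and under quantile normalization, median centring and the authors' values (0 probes each), while leaving dim probes in gave 38 (9 higher, 29 lower). The 3 water controls were read on a scan day of their own, so no value within a day could be had. With scan day as a random block 68 probes passed (58 higher, 10 lower). The fitted correlation within days was negative (−0.21), which shrinks the error of a difference between days by construction, so this count does not correct for scan day.

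The second comparison asked what acetone, often used to carry poorly soluble chemicals into test soil, does by itself within 2 days. With acetone, 55 of 883 probes changed relative to the water control, 19 higher and 36 lower. The higher ones differed by a median of 22.2-fold (2.46 to 80.7) and the lower ones by 2.39-fold (1.64 to 5.22). Contig8 rose by 6.33 ± 1.16 (SE) on the log2 scale (adjusted p = 0.0194), an 80.7-fold difference. It was at 2.89 ± 0.09 (SD, n = 3) with acetone and at −3.44 ± 3.02 (SD, n = 3) in the controls, whose 3 replicates were at 0.01, −4.73 and −5.60. Ealb_Met_P7_C1_SP6_2090602 rose by 6.28 ± 1.19 (SE; adjusted p = 0.0217), 77.8-fold, from −3.52 ± 3.12 to 2.76 ± 0.05 (SD, n = 3 each). Its 3 controls were at 0.03, −4.73 and −5.85, close to those of Contig8, so the 2 rises may not be separate observations. Contig129 fell by 2.38 ± 0.29 (SE; adjusted p = 0.0121), from −1.46 ± 0.31 to −3.85 ± 0.55 (SD, n = 3 each). Ealb_Met_P6_G2_SP6_2090523 fell by 2.38 ± 0.61 (SE; adjusted p = 0.0498), from −4.51 ± 1.25 to −6.89 ± 0.54 (SD, n = 3 each), but lost the threshold in 14 of 18 other settings (adjusted p up to 0.662, log2 differences of −3.03 to −1.03). For each of the 55 probes the 3 acetone samples lay beyond all 3 controls, which held for 330 of the 883 probes tested (10% by chance).

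The balance of higher and lower calls with acetone moved with the scaling of the arrays and with the fit. Scaled to the 75th percentile, the median probe was at −0.31. This shift was not removed, so each difference given above includes it, and 34.5% of calls were higher. After quantile normalization the median was −0.07 and 22 probes passed, 20 higher and 2 lower. With arrays centred on their median it was 0.05 and 22 passed, 21 higher and 1 lower. Each of these settings kept 19 of the 55 probes. The authors' values gave 4 (3 higher, 1 lower), and normexp background correction gave 31 (16 higher, 15 lower). At unchanged scaling the joint fit of all samples gave 13 higher and 0 lower, the replicate block 14 and 1, and the fit without water control replicate 3 gave 9 and 1. Contig8 and Ealb_Met_P7_C1_SP6_2090602 did not pass in the authors' values (adjusted p = 0.0833 and 0.0865), where they differed by 6.41 and 6.35, nor in the fit of only these 2 groups (0.0504 each), nor in 4 of 6 fits with a replicate left out (up to 0.0910 and 0.101). Contig129 passed in all settings but the joint fit of all samples (adjusted p = 0.711). Leaving out acetone replicate 2 left 1 probe, water control replicate 2 left 5, water control replicate 3 left 10 and acetone replicate 1 left 22. No scan day held both groups. With scan day as a random block 243 probes passed (29 higher, 214 lower), but the fitted correlation within days was again −0.21, so this count is no better guide.

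**Figure D3:**
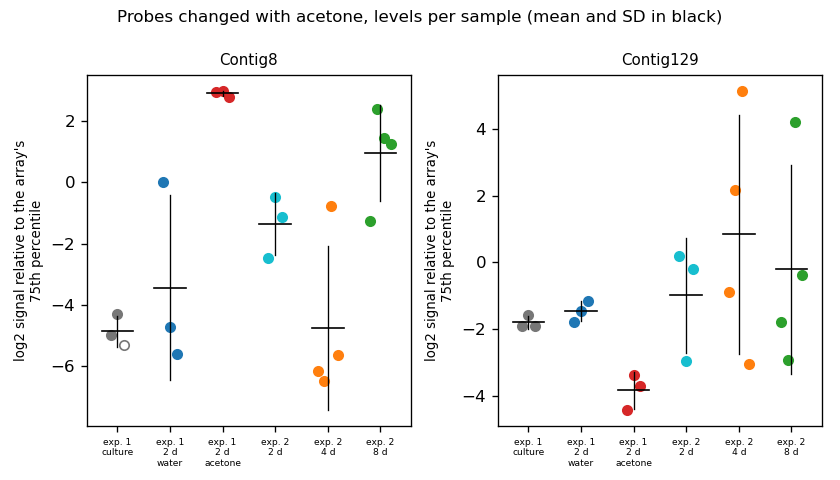
The log2 level relative to the 75th percentile of the array is plotted for Contig8 and Contig129 in each sample of the 6 groups, with the group mean and SD in black; open symbols are samples in which the probe was not well above background. Contig8 averaged 2.89 with acetone and −3.44 in the water controls of experiment 1, and Contig129 averaged −3.85 and −1.46.

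The third comparison asked whether worms in control soil differ after 4 and 8 days from worms after 2 days. At 4 days, 4 of 859 probes changed, 3 higher and 1 lower. P2_B7_T7_1328934 was at −3.02 ± 1.08 (SD, n = 4) at 4 days and was not well above background on any 2-day array (measured mean −9.51 ± 1.12 SD, n = 3), a difference of at least 21.5-fold (adjusted p = 0.0194). The bound sets the 4-day mean against, per 2-day array, the higher of the probe's own signal and the lowest signal among probes well above background. P5_A4_T7_1329813 rose by 2.95 ± 0.48 (SE; adjusted p = 0.0194), from −4.97 ± 0.62 (SD, n = 3) to −2.03 ± 0.75 (SD, n = 4). Its 2-day level was the lowest of all groups: it averaged −1.66 in culture, −0.35 in the water controls and −1.27 with acetone in experiment 1, and −2.97 at 8 days. Ealb_Met_P6_H9_SP6_2090577 fell by 2.23 ± 0.35 (SE; adjusted p = 0.0194), from 1.90 ± 0.31 (SD, n = 3) to −0.33 ± 0.51 (SD, n = 4). The fourth, P1_E4_T7_1328836, named here because the list was so short, rose by 1.91 ± 0.36 (SE; adjusted p = 0.0449). Ealb_Met_P5_H9_T7_2175272 differed by −2.16 and did not pass (adjusted p = 0.0508). The median probe differed by −0.26 under this scaling and by 0.01 after quantile normalization, where 2 of the 4 probes passed, 1 higher and 1 lower. With arrays centred on their median 2 of the 4 passed, both higher, and in the authors' values 2 of the 4, 1 in each direction.

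The 4-day calls rested on few arrays. No probe passed without 2-day replicate 1, without 2-day replicate 3 or without 4-day replicate 1, whereas 17 passed without the averaged 2-day pair and 11 without 4-day replicate 4. With arrays 2 and 4 of the 2-day group as separate samples, 9 probes passed (3 higher, 6 lower). Leaving out the 3 dimmest arrays of experiment 2 leaves 1 sample at 2 days, so no count is given, and the median probe differed by 0.04. 4-day replicates 1 and 2 were read on a newer scanner model than the other 19 arrays: 34 probes passed with these 2 arrays alone and 0 with the other 2. No scan day held 2 groups of time points in experiment 2; with scan day as a random block 3 probes passed.

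At 8 days no probe passed against 2 days (limma, 0 of 859 probes; 42 had an unadjusted p under 0.05; smallest adjusted p = 0.259). Contig51 was at −0.10 ± 1.79 (SD, n = 4) at 8 days and −4.90 ± 1.04 (SD, n = 3) at 2 days, a difference of 4.79 ± 0.96 (SE; adjusted p = 0.259). Contig135 differed by 2.74 ± 0.60 (SE; adjusted p = 0.259), Ealb_Met_P4_B1_SP6_2090421 by −1.77 (adjusted p = 0.454) and P4_5D_T7_1329751 by −1.67 (adjusted p = 0.473). The median probe differed by −0.16. On simulated data with the spread of these arrays and 200 changed probes, 23.3% of probes changed by 1 log2 unit, 69.6% of those changed by 2 and 89.5% of those changed by 3 were found; with fewer changed probes the adjusted threshold is harder to pass. Fitting only these 2 groups gave 5 probes, all higher at 8 days.

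A test of 8 against 4 days, which the design text does not name, gave 9 of 859 probes, 8 higher at 8 days and 1 lower. Ealb_Pest_P6_F12_SP6_2092122 rose by 3.44 ± 0.61 (SE; adjusted p = 0.0312), from −2.92 ± 1.40 to 0.52 ± 0.51 (SD, n = 4 each), and Contig135 rose by 3.33 ± 0.56 (SE; adjusted p = 0.0299), from −4.69 ± 1.31 to −1.35 ± 0.37 (SD, n = 4 each). P2_B7_T7_1328934 was at least 16.0-fold lower at 8 than at 4 days (adjusted p = 0.0213), with a measured mean of −9.19 ± 1.94 (SD, n = 4) at 8 days, where it was not well above background on any array. It and Ealb_Met_P6_H9_SP6_2090577 also changed between 2 and 4 days, each in the opposite direction. The 8 higher probes differed by 3.26-fold to 52.4-fold. Over all 3 time points together, 5 probes passed the moderated F test, each of them called between 2 and 4 or between 4 and 8 days. Only the lower of the 9 probes passed after quantile normalization, with median centring or without the 3 dimmest arrays (1 probe each). None passed without 4-day replicate 1, 2 or 4 or 8-day replicate 2 or 4, 4 passed without 8-day replicate 3, and with scan day as a random block none passed in this test or in the F test. With 4-day replicates 1 and 2 of the newer scanner alone 20 probes passed, and with replicates 3 and 4 alone 1. The F test gave 10 probes without the averaged 2-day pair, 13 without 4-day replicate 3, 3 without 4-day replicate 4, 1 without 2-day replicate 3 or 8-day replicate 3 and 0 without any of the other 6 samples.

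**Figure D4:**
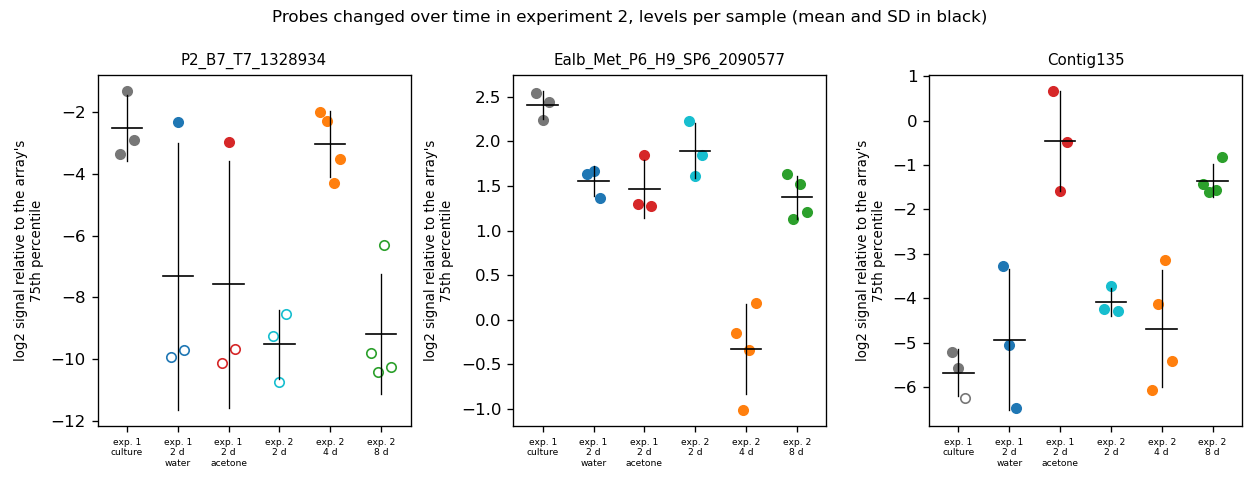
The log2 level relative to the 75th percentile of the array is plotted for P2_B7_T7_1328934, Ealb_Met_P6_H9_SP6_2090577 and Contig135 in each sample of the 6 groups, with the group mean and SD in black; open symbols are samples in which the probe was not well above background. In experiment 2, P2_B7_T7_1328934 averaged −9.51, −3.02 and −9.19 at 2, 4 and 8 days, Ealb_Met_P6_H9_SP6_2090577 averaged 1.90, −0.33 and 1.37, and Contig135 averaged −4.09, −4.69 and −1.35.

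Worms after 2 days in control soil were measured in both experiments, and 66 of 889 probes differed between these groups, 25 higher in experiment 2 and 41 lower. P1-9G_T7_821247 rose by 3.42 ± 0.46 on the log2 scale (SE; adjusted p = 0.0131), at −0.59 ± 0.61 against −4.01 ± 0.67 (SD, n = 3 each). Contig41 was at least 2.31-fold higher (adjusted p = 0.0477) and was not well above background on any control array of experiment 1. P5_A4_T7_1329813 fell by 4.62 ± 0.43 (SE; adjusted p = 0.00898), from −0.35 ± 0.55 to −4.97 ± 0.62 (SD, n = 3 each), and P1_F7_T7_1328858 fell by 4.17 ± 0.61 (SE; adjusted p = 0.0131), from 1.89 ± 0.21 to −2.28 ± 1.25 (SD, n = 3 each). Of the probes whose identifiers give only a plate position, 5 were higher and 28 lower, out of 273. As a class chosen after the data were seen, they moved down against the other probes (mean log2 difference −0.41 against 0.44; adjusted p = 2.92e-13, and adjusted p = 0.00538 with an estimated correlation). The median probe differed by 0.33, by 0.09 after quantile normalization (110 probes) and by 0.24 with median centring (94 probes). No probe passed without water control replicate 2 or 3 of experiment 1 or without 2-day replicate 1 of experiment 2, 1 passed without water control replicate 1, 35 without 2-day replicate 3 and 516 without the averaged pair. These groups shared no scan day, and with scan day as a random block 0 probes passed. In that fit the 3 water controls were 1 block and each sample of experiment 2 was a block of its own. That fit cannot tell likeness within a day from the smaller spread in experiment 1, so the 0 says nothing about scan day. With the 2 near-identical arrays as separate samples 134 passed. Without the dimmest arrays only the averaged pair was left at 2 days in experiment 2, and the median probe differed by −0.03. The spread then came from the steadier water controls of experiment 1 alone, so the count is not given.

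The overlap between comparisons that share control samples was set against simulations of unchanged groups. Changes from culture to soil and changes with acetone share the water controls: across probes, which are not independent, r was −0.13 (Spearman's rho −0.41), against −0.46 ± 0.25 (SD) in 100 simulations. The covariance was −0.055 against a simulated −0.081, and no call was shared (0.02 expected of independent lists). Changes at 4 and at 8 days against 2 days share the 2-day samples: r was 0.50 (rho 0.55) against 0.57 ± 0.26 simulated, and the covariance 0.31 against 0.26. With no call at 8 days none could be shared, and 5 higher probes were shared at an unadjusted p under 0.01, with 0.29 expected of independent lists and a mean of 1.90 (at most 48) in the simulations, both directions together. With 3 control samples the controls could not be split, so part of any excess may come from the shared controls.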

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

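The tests of acetone against culture for the scan day, that of probes picked with the newer scanner alone, the test of bright probes in 8-day replicate 3, and the use of the spread of the spike-in probes to read their shift, were chosen after the results were seen. A single sample far from the others of its group was looked for in 44 groups of values of 4 samples each and found in 5, where chance gives about 1 in 20. Groups of 3 samples were not searched, so culture replicate 3, with the fewest probes well above background of all arrays (599), could not be found. Contig51 was at −5.81 in 4-day replicate 1, with the others between −3.40 and −3.14. In 4-day replicate 3, Contig8 was at −0.78 (others −6.47 to −5.62) and Ealb_Met_P7_C1_SP6_2090602 at −0.25 (others −6.78 to −5.71). These 2 probes moved closely together over the samples, so they do not count as separate findings among the 5. In 8-day replicate 3, 669 probes were well above background (902 to 919 in the others), and P2_B7_T7_1328934 was at −6.30 (others −10.4 to −9.79) without being well above background in any of the 4. The changes from 2 days to 4 and to 8 days differed from each other for 9 probes, which is the test of 8 against 4 days.

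Of these, 8-day replicate 3 belongs to a wider pattern: it and 2-day replicates 1 and 3 of experiment 2, the 3 dimmest arrays there, stood apart from all other samples. Signals near background cannot be told apart: among the brightest 322 probes the dim and other 2-day samples differed with a MAD of at least 0.891 (bootstrap lower limit 0.752, below the 0.8 set), against 0.461 between the 2 dim ones, but 8-day replicate 3 differed from its group by only 0.596 to 0.811, against at most 0.692 among the others. Scan day and slide do not separate 2-day replicates 1 and 3 from the rest. 2-day arrays 1 and 2 shared both and differed with a MAD of 1.15, and arrays 3 and 4 shared both and differed with 1.20. Scan day does not separate 8-day replicate 3 either: it shared the day, though not the slide, with replicate 4 and differed with a MAD of 1.29. Lower sensitivity of the hybridisation may contribute and cannot be told apart: the 4 spike-in probes used shifted by −0.83 log2 units (SE 0.57) on the dim arrays, near the −0.99 of the worm probes, but the spike-in mean varied with an SD of 0.86 among the other arrays. A difference between the worms or extracts stays open too, and no biological explanation was tested, since the labels do not tell these samples from the rest.

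For acetone, all 3 control arrays were read on a day on which no acetone array was read. For the 19 higher probes, acetone minus culture arrays, none read on that day, gave a median of 5.22 log2 units. The calls had 4.47, and 19 of 19 went in the same direction. This argues against the day of the control arrays as the only source of these calls, but does not exclude a part in them. The 19 linked probes were picked with these same acetone arrays, and acetone and culture worms also differ by the 2 days in soil. For the 36 lower probes the difference between acetone and culture arrays was 0.875 in the direction of the call, against 1.26, for 36 of 36. Its bootstrap SE was 0.095, over probes that are linked. This was too close to the bound of 0.837 set for it, so day and acetone cannot be told apart there. The scaling cannot be set aside for these probes either: 2 lower calls were left after quantile normalization and 1 with median centring. The 1 acetone array read on a day with culture arrays gave a median of 1.04 over the 55 probes, 54 in the direction of the call, but a single array excludes nothing. An effect of acetone stays open as a hypothesis, and of the 10 splits of the 6 samples, 1 gave 55 or more calls, the real one; the others gave at most 0, too few splits for a share under 0.05.

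The 4 probes called at 4 days might reflect the newer scanner of replicates 1 and 2. The 2 arrays of the older scanner alone gave a median difference of 2.19 log2 units in the direction of the calls, against 2.59 in the calls and 2.98 on the newer scanner, but the calls were picked with these arrays among the 4. The 34 probes called with the newer arrays alone, the 4 among them, differed by a median of 2.69, and the older arrays by 0.991 in the same direction (28 of 34), between the bounds set, so scanner and time cannot be told apart; the older arrays alone gave 0 calls. An effect of time stays open as a hypothesis: of 35 splits of the 7 samples, 1 gave 4 or more calls, the real one, and the others at most 3, a share under 0.05 that excludes chance only if samples exchange freely, whereas samples of 1 scan day were alike (correlation 0.37) and the count was 3 with scan day as a random block.

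For the other comparisons, splits of the same samples into groups of the same sizes gave the following. From culture to soil, 1 of 10 splits gave the real count of 1, the others at most 0, and between the experiments 1 of 10 gave the real 66, the others at most 6; neither has enough splits for a share under 0.05. At 8 against 4 days 1 of 35 splits gave 9 or more, the others at most 3, which excludes chance under the same condition only, and with scan day as a random block the count was 0. At 8 against 2 days the real count was 0, which all 35 splits reach by definition, so the test says nothing about chance there; the highest other gave 161 and set the 3 dim arrays against the rest, which points to a structure of the samples. For any time point 3 of 100 splits drawn gave 5 or more, and 1 of the others gave 157, with the 3 dim arrays and 4-day replicate 2 in 1 group; with scan day as a random block the count was 0 there too.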

How the results depend on the processing

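No setting reversed any single named probe: of their values, 321 kept direction and side of the threshold, 124 lost the threshold and 20 gained it. Of the counts of changed probes, 50 stayed within 1.5 times and 100 did not. The kept directions say little about robustness. The named probes were picked for large or clear differences, mostly between groups that did not overlap, and several settings change only the error of a difference. Where no reason is given, the cause was not tested. The filter on dim probes changed the counts: without it they were 38 for culture to soil, 33 for acetone, 1 at 8 against 2 days and 3 for any time point, against 1, 55, 0 and 5. With only probes above background on every array they were 3, 31 and 2 (4 against 2 days).

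In the order culture to soil, acetone, 4 against 2, 8 against 4 days, any time, quantile normalization gave 0, 22, 2, 1 and 1 probes and median centring 0, 22, 2, 1 and 1, against 1, 55, 4, 9 and 5; between the experiments quantile normalization gave 110 against 66. The authors' values gave 0, 4 and 2 for the first 3. Normexp on median signals gave 31 for acetone, 1 at 4 against 2 days and 43 between experiments; normexp on mean signals, as planned, was not run because the files hold no such column. The intensity trend gave 2 for culture to soil. Fits of only the compared groups gave 8, 22, 1, 5 (8 against 2 days) and 0 (8 against 4 days). All samples in 1 fit gave 0, 13, 40, 1, 17 and, for any time, 35.

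Samples were not treated as paired by replicate number, since in no pair of groups did all same-numbered samples reach a correlation of 0.1 (−0.098 to 0.591 for 2 and 8 days). For water and acetone the 3 same-numbered pairs were all positive (0.071 to 0.239), so some pairing there is not excluded. All others were negative (−0.223 to −0.000270). The correlations are of deviations from group means, so positive same-numbered pairs make the others negative on balance, which is no separate support. The replicate block gave 0 for culture to soil, 15 for acetone (14 higher, 1 lower), 1 at 4 against 2 days, 0 at 8 against 4 days, 0 for any time and 0 between experiments. As a random block, scan day gave 68, 243, 0 (8 against 4 days), 0 (any time) and 0 (experiments), and slide 17 and 83. The correlation within days was −0.21 in experiment 1, within slides −0.25, and a negative correlation shrinks the error of a difference between days by construction. The correlation within days was 0.37 in experiment 2 and 0.84 between experiments. Slide could not be fitted there, with only 1 slide holding 2 samples. The 0.84 does not measure likeness within days. The water controls were all on 1 day and each sample of experiment 2 was its own block, so it reflects the smaller spread in experiment 1.

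After seeing the data, arrays 2 and 4 of the 2-day group were also kept apart (9 at 4 against 2 days, 11 for any time, 134 between experiments), the 3 dimmest arrays left out (1 at 4 against 2, 1 at 8 against 4 days, 1 for any time, 135 between experiments; except at 8 against 4 days this leaves 1 sample at 2 days, assumed to vary like the other groups), and the 4-day arrays of the older scanner used alone (0, 1 and 0 for 4 against 2, 8 against 4 days and any time) or of the newer (34, 20 and 26).

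Leaving out each replicate in turn gave 0 to 0 probes for culture to soil, 1 to 39 for acetone, 0 to 17 at 4 against 2, 0 to 0 at 8 against 2, 0 to 11 at 8 against 4 days, 0 to 13 for any time and 0 to 516 between experiments; fewer samples enter these fits. Without water control replicate 2 or 3 or 2-day replicate 1 the count between experiments went from 66 to 0, and without the averaged 2-day pair to 516; without acetone replicate 2 that for acetone went from 55 to 1. The median SD in the water controls of experiment 1 was 0.134 with normexp and 0.113 to 0.193 with a replicate left out, against 0.204; at 2 days in experiment 2 it was 0.220 to 0.638, lowest without the averaged pair, against 0.591. In the other groups it ranged from 0.269 to 0.342 (acetone), 0.203 to 0.263 (culture), 0.607 to 0.712 (4 days) and 0.380 to 0.555 (8 days).

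Probes shared at an unadjusted p under 0.01 were counted in either direction. Culture to soil shared 5 with acetone (all 5 in opposite directions), 6 with 4 against 2 (0 opposite), 1 with 8 against 2 (0 opposite) and 1 with 8 against 4 days (opposite), and 12 with the experiments (11 opposite), with 0 each among calls. Acetone shared 4 with 4 against 2 (2 opposite), 7 with 8 against 2 (1 opposite) and 11 with 8 against 4 days (1 opposite), with 0, 0 and 7 among calls, and 6 with the experiments (0 opposite, 1 call). Changes at 4 against 2 days shared 5 with 8 against 2 (0 opposite), 8 with 8 against 4 days and 21 with the experiments (all opposite), with 0, 2 and 1 among calls. Changes at 8 against 2 days shared 8 with 8 against 4 days (0 opposite) and 7 with the experiments (6 opposite), and 8 against 4 days shared 3 with the experiments (0 opposite), with 0 each among calls, where 8 against 2 days had none to share. Comparisons that have a group on opposite sides can move in opposite directions without any change: in 100 simulations of unchanged groups the opposite probes averaged 1.63 (at most 34) for culture to soil with acetone, 0.76 (27) for culture to soil with the experiments, 2.59 (84) for 4 against 2 with 8 against 4 days, and 2.04 (34) and 3.40 (79) for 4 and 8 against 2 days with the experiments. In that order, 9, 1, 7, 3 and 12 of the 100 simulations reached the real number. The shared group alone thus seldom gave as many for culture to soil or for 4 against 2 days with the experiments. The mean of the Pest class relative to other probes at 8 against 4 days turned to −0.00312 with quantile normalization (adjusted p = 0.626).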

Other observations

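The tests of whether the overlap described next exceeds chance were chosen after the overlap was seen. A set of 7 probes, among them Contig8, Contig135 and Ealb_Pest_P6_F12_SP6_2092122, was higher both with acetone at 2 days in experiment 1 (log2 differences 4.47 to 6.33) and at 8 against 4 days in experiment 2 (3.26 to 5.71). These comparisons share no arrays, but acetone replicates 2 and 3 and 8-day replicates 3 and 4 were read on 1 scan day, and replicate 3 of each was on the same slide. In samples read on other days the set was at 1.74 (acetone replicate 1) and at −0.93 and 0.06 (8-day replicates 1 and 2), against 0.49 and 1.05 with acetone and −0.48 and 0.12 at 8 days on that day. The mean level of the set was 1.09 ± 0.63 (SD, n = 3) with acetone and −0.31 ± 0.49 (n = 4) at 8 days, against −4.57 ± 0.24 (n = 3) in culture, −3.86 ± 2.06 (n = 3) in the water controls, −2.94 ± 0.64 (n = 3) at 2 days and −3.96 ± 1.52 (n = 4) at 4 days in experiment 2. Water control replicate 1 was at −1.65 and 4-day replicate 3 at −1.94, above the other replicates of their groups. Against 2 days, none of the 7 passed at 8 days: Contig135 differed by 2.74 and Contig8 by 2.32 (adjusted p = 0.259 and 0.984). None of the 7 passed at 8 against 4 days after quantile normalization, with median centring or without the 3 dimmest arrays (for Contig135, adjusted p = 0.0562, 0.0731 and 0.120), so the shared calls depend on the processing.

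Independent lists of 17 and 8 higher calls among the 848 probes tested in both would share 0.16, but the probes are linked. Lists of these sizes, drawn from 100 simulations of unchanged groups that keep linked probes linked, shared 0.30 on average and at most 4. At an unadjusted p under 0.01 the real lists shared 10 in the same direction (simulated mean 1.09, at most 5). Because the pair was picked after the overlap was seen, the 6 pairs of a comparison within experiment 1 with one within experiment 2 were searched in each simulation. In 3 of 100 any of them shared 10 or more. The pair of 8 against 4 days with the difference between experiments also shares no arrays but was not searched. The 3 of 100 argue against chance among these 6 pairs, although the simulations ignore the scan days. Over all probes r was 0.38 but rho −0.14. Part of the set may be 1 transcript, or tightly linked transcripts, measured several times: within groups its probes varied together with a median pairwise r of 0.953 (lowest 0.661), against at most 0.498 in 100 random sets of 7. The 15 of 21 pairs above 0.9 were those among the 6 probes other than Contig8, which correlated with them at 0.661 to 0.805 and differed by −3.39 at 4 against 2 days, where the 6 differed by −0.66 to −0.60. The 6 would then not count as 6 separate observations. The 19 probes higher with acetone likewise fell into 7 clusters at a correlation of 0.7, the largest with 10 members (median pairwise r 0.356), and the 36 lower ones had a median pairwise r of 0.679 with 87 of 630 pairs above 0.9, so neither are these all separate observations.

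Some probes varied over a wide range from sample to sample. Over the 20 samples, 52 probes had a measured range above 6 log2 units; 15 of them were well above background in all samples, and for the other 37 the low levels are not exact. Within single groups 4 did so in the water controls, 2 with acetone, 4 in culture, and in experiment 2 there were 3 such probes at 2 days, 11 at 4 days and 6 at 8 days. P1_B6_T7_1328848, singled out after its values were seen, was in the 4-day group not well above background in replicates 1 and 2 and at −3.99 and 2.50 in replicates 3 and 4. Ealb_Met_P3_F12_SP6_2090417, singled out in the same way, had the widest measured range of the 15, 11.5: it was between 4.12 and 6.03 in each sample of experiment 1 and of the 2-day group of experiment 2, but at −4.66, −3.49 and −5.50 in 4-day replicates 1, 2 and 3 and at 1.73 in replicate 4, and at 4.85, 2.44, 2.52 and −2.23 in 8-day replicates 1 to 4. With the array's 75th percentile added back, its log2 signal was nearly the same on all arrays of experiment 1, as that of a saturated probe would be. Saturated spots were kept, so its high levels and its range are not exact and may be too low. A single source shared by all these transcripts, such as another organism or a body part present in some samples, could make them move together. The median absolute rank correlation over their 1326 pairs was 0.273, above the highest of 100 shuffles (0.168). It was far below the 0.7 set beforehand as the bound for 1 source, while 7.24% of pairs exceeded 0.8. Among the 15 it was 0.292 (highest shuffle 0.214; 12.4% of pairs above 0.8). Both values fall short of the bound, but the bound was not checked on probes of a known single source. So 1 source for all of them is neither shown nor excluded, and smaller linked sets stay open.

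The classes read from probe identifiers, chosen after the data were seen, moved as follows against the other probes. Plate-only probes were higher from culture to soil (adjusted p = 0.00537, and adjusted p = 0.365 with an estimated correlation) and at 4 against 2 days (2.11e-05 and 0.145), and lower at 8 against 4 days (0.00129 and 0.332). Contigs were lower at 4 against 2 days (0.00271 and 0.549) and higher at 8 against 4 days (0.0190 and 0.620), as were Pest probes at 8 against 4 days (0.0190 and 0.620). Between the experiments contigs (5.59e-05), Met (0.0337) and Pest probes (0.0248) were higher in experiment 2, each with an adjusted p of 0.585 with an estimated correlation. Thus only the lower plate-only class between the experiments passed with both. No class passed with acetone or at 8 against 2 days, and for contigs with acetone and Met probes at 8 against 4 days the median and the mean differed in sign relative to the other probes.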
